A study of Homo sapiens with 12 samples.

How the data were processed

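Bulk RNA sequencing was measured in human monocyte-derived macrophages, which are blood monocytes differentiated in culture, from 2 donors, called A and B here. Cells of each donor received DMSO, the solvent control, or 1 µM TAK-981 for 24 h, in 3 cultures per donor and treatment, which the labels call biological replicates. The 12 libraries form 4 groups of 3, taken from the sample labels, and TAK-981 was compared with DMSO over both donors, within each donor and between donors.

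The deposited table holds expected counts, estimated reads per gene, as whole numbers for 57730 gene rows and 12 libraries, and no column belonged to an unlisted sample. FastQC, STAR, RSEM and edgeR 3.8.5 were used, per the submitters' processing notes, which give no role or order. The genome build, annotation release and strand setting are not given in the sources used here, so no coordinates are printed. Rows carry an Ensembl identifier and a symbol, and symbols are printed as the table gives them. RSEM divides reads that match several genes between them by an estimate, so levels of near-identical copies are uncertain (FCGR1A and its relatives, FCGR2B and FCGR2C, FCGR3A and FCGR3B, MRC1 and its duplicate, HSPA1A and HSPA1B, HLA genes, histone genes and ribosomal proteins with pseudogenes). Levels of genes overlapping an antisense partner are uncertain too. A total of 521 rows for genes of the Y chromosome, their pseudoautosomal copies, XIST and TSIX were left out of every step, which left 57209 rows, of which 29029 had a count in some library.

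Total counts per library lay between 41569846 and 65842731. Levels are in CPM, counts scaled by library size and TMM factor. A count of 3 in a library, the floor used for genes with no count, came to between 0.0418 and 0.0966 CPM after scaling. The highest DMSO floor was used for each fold change against a gene with no count in DMSO. Floors cover counting error only, since reads without molecular identifiers are not independent molecules.

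Differential expression was tested in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr on the 4 groups, which kept 16233 genes. Libraries were scaled with TMM factors. Quasi-likelihood F tests (glmQLFit with robust estimation, glmQLFTest) were adjusted over the genes tested by the Benjamini-Hochberg method, and a gene was called at an adjusted p below 0.05 in either direction. The comparison over both donors had an additive donor term. The comparisons within a donor and the difference of the response between donors were contrasts of the 4 group means, so all 12 libraries shared 1 estimate of the spread. Levels are TMM-scaled CPM as mean ± SD over the 6 libraries of a treatment, so that SD also holds the difference between donors. Fold changes are log2 of TAK-981 over DMSO ± SE, with SE taken as the size of the log2 fold change divided by the square root of F. With 2 donors the spread between people cannot be estimated, and the p-values measure the spread between cultures.

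The 33 gene lists and the marker lists of other cell types among them were fixed before the data were examined, as were the tests and the alternatives, except where stated. Lists with at least 5 tested genes were compared with all other genes by camera (edgeR with limma 3.58.1, preset inter-gene correlation 0.01), adjusted over the 33 lists. Camera with an estimated correlation was an alternative, and fry was run beside it. Library totals and shares of counts were compared by an exact two-sided permutation test of the mean of the within-donor differences, over 400 assignments of treatment within donors, which cannot give a p below 0.005. Correlations of fold changes run across genes, which are not independent replicates, and carry no p.

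The genes named are the 8 largest rises and 8 largest falls among genes called over both donors and in each donor with the same sign and a mean of at least 5 CPM, excluding uncharacterised loci, antisense and small RNA names. A fixed set was named beside them (SUMO2, SUMO3, SAE1, UBA2, IFNB1, IFNL1, IRF7, ISG15, MX1, IFIT1, CXCL10, FCGR1A, FCGR2A, FCGR2B, FCGR3A, CD80, CD86, CD40, CD163, MRC1 and 3 genes that are not reported here). Up to 4 members per list with the smallest p were named, and up to 4 genes per direction with the largest difference between donors among those called with at least 5 CPM in all 4 groups. Immunoglobulin and T cell receptor genes, HLA genes in the donor difference, and genes with common whole-gene deletions were never named.

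The alternatives were RLE size factors, library totals only, no filter beyond 1 count, a filter of at least 50 counts in 3 libraries, DESeq2 1.42.0 (Wald test on the same genes), the replicate number as a block, no donor term, the mean of the within-donor contrasts, each donor's own 6 libraries, an estimated correlation for the lists and other denominators for the shares. Each library was also left out in turn. Leaving out both donor A replicate 2 libraries together was added after the data were seen. The 3 replicates of a group differed by more than counting noise in every pair, with a chi-square per degree of freedom of at least 5.56, so none was taken for a duplicate of another. That they are separate samples rests on the labels.

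The gene tests were tested on simulated counts drawn for the real genes and library sizes, with 100 genes changed 2-fold and 100 changed 4-fold. The simulated spread between replicates was a single fixed dispersion, lower than the common dispersion of the data, 0.0991, and no simulated library stood apart. The shares below therefore hold for cleaner data than these. For the comparison over both donors, on 15535 genes, 97% of genes changed 4-fold and 88% of genes changed 2-fold were recovered, and 4.6% of calls were unchanged genes. Within donor A, on 15528 genes, 91% and 46% were recovered at those folds, and within donor B, on 15536 genes, 96% and 43%. Of the calls within donors A and B, 2.1% and 5.4% were unchanged genes. For the difference between donors, on 15531 genes, 82% of 4-fold and 15% of 2-fold differences were recovered. Camera recovered 5 of 5 planted lists and called 0 of 40 unchanged lists. The simulated genes varied independently, so this does not show how often camera calls unchanged lists whose members vary together. Matching on transcript length used median transcript lengths of the reference annotation for 96.6% of the tested genes, joined by Ensembl identifier.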

Results

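The study measured gene expression in human monocyte-derived macrophages after exposure to TAK-981 (subasumstat), a small-molecule inhibitor of the SUMO-activating enzyme, the SAE1 and UBA2 dimer that starts conjugation of the small protein modifier SUMO to other proteins. Macrophages of 2 donors were cultured with DMSO or with 1 µM TAK-981 for 24 h, with 3 cultures per donor and treatment. The 12 libraries held between 41569846 and 65842731 counts, and totals did not differ between treatments (exact permutation within donors, p = 0.87). The first principal component, with 55.7% of the variance, separated the treatments. The second, with 29.1%, separated the replicate 2 libraries of donor A, of both treatments, from the other 10. Between libraries of a group, log2 CPM correlated at 0.993 or more in donor B, but at 0.899 to 0.982 in donor A with DMSO and 0.944 to 0.992 in donor A with TAK-981. Those 2 libraries also had the lowest TMM factors, 0.748 and 0.772.

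**Figure D1:**
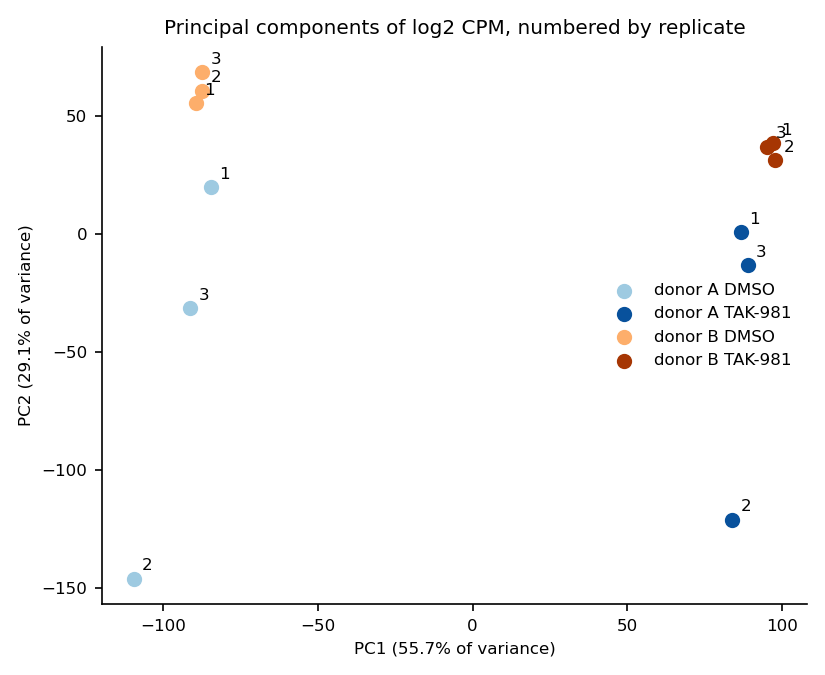
Each point is 1 library, numbered by replicate, placed by the first (horizontal, 55.7% of the variance) and second (vertical, 29.1%) principal components of log2 CPM and coloured by donor and treatment. The treatments lie at opposite ends of the horizontal axis, and both replicate 2 libraries of donor A lie below the other 10 on the vertical axis.

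The first comparison asked how inhibition of SUMO conjugation changed the macrophage transcriptome over both donors. Interferon-stimulated genes rose together: all 61 tested members of the list fixed beforehand were called higher, with a median log2 fold change of 4.89. IFIT1, which encodes an antiviral RNA-binding protein, went from 20 ± 8.45 CPM with DMSO to 7170 ± 431 CPM with TAK-981 (SD, n = 6 per treatment). The chemokine gene CXCL10 went from 2.86 ± 2.28 to 4250 ± 385 CPM. IFNB1, the gene of interferon beta, had no count in any DMSO library and reached 228 ± 204 CPM with TAK-981, at least 2360-fold higher against a floor of 3 counts per library. Without donor A TAK-981 replicate 2, which had the highest IFNB1 level, the mean was 148 CPM and the bound 1530-fold. Falls were led by KLHL13, LGI2 and ZNF704, and the scavenger receptor family gene CD163L1 dropped from 485 ± 149 to 19 ± 6.19 CPM. In the edgeR quasi-likelihood test 8900 of 16233 genes were called, 4463 higher and 4437 lower. Of these, 2572 rose and 2680 fell by over 1 log2 unit.

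Among the 8 largest rises that met the naming rule were CXCL11, the gene of a chemokine that shares a receptor with CXCL10, and IDO1, an enzyme gene of tryptophan breakdown. Their log2 fold changes were 13.20 ± 0.58 and 11.30 ± 0.50, and that of the cytidine deaminase gene APOBEC3A was 10.90 ± 0.31. LGALS17A rose from 0.0132 ± 0.0258 to 66.3 ± 30.9 CPM and DEFB1, which encodes a defensin, from 0.0505 ± 0.0591 to 158 ± 116 CPM. Without donor A DMSO replicate 2 the DMSO means were 0.00303 CPM for LGALS17A, whose log2 fold change moved from 12.60 to 13.60, 0.0284 CPM for DEFB1 and 0.0876 CPM for IDO1 (0.148 with it). The DMSO mean of CXCL11, 0.199 CPM, is lower by over 1.5 times without donor A DMSO replicate 1, which had 0.57 CPM. HRASLS2 and TRIM31 had no count with DMSO and were at least 131-fold and 108-fold higher with TAK-981. The largest falls were those of KLHL13 at -5.76 ± 0.52, LGI2 at -5.71 ± 0.18, ZNF704 at -5.42 ± 0.24 and SH3RF3 at -5.31 ± 0.14. They were followed by RRM2, a ribonucleotide reductase subunit gene, at -5.20 ± 0.21, BNC2 at -5.04 ± 0.33, GPRC5B at -5.02 ± 0.15 and CD163L1 at -4.67 ± 0.17. Adjusted p in edgeR's test was 3.86e-06 or less for these 16 genes, and each was called in both donors. With library totals in place of TMM factors the median over all genes moved from -0.04 to -0.22 and the share of calls that were higher from 50.15% to 38.95%.

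**Figure D2:**
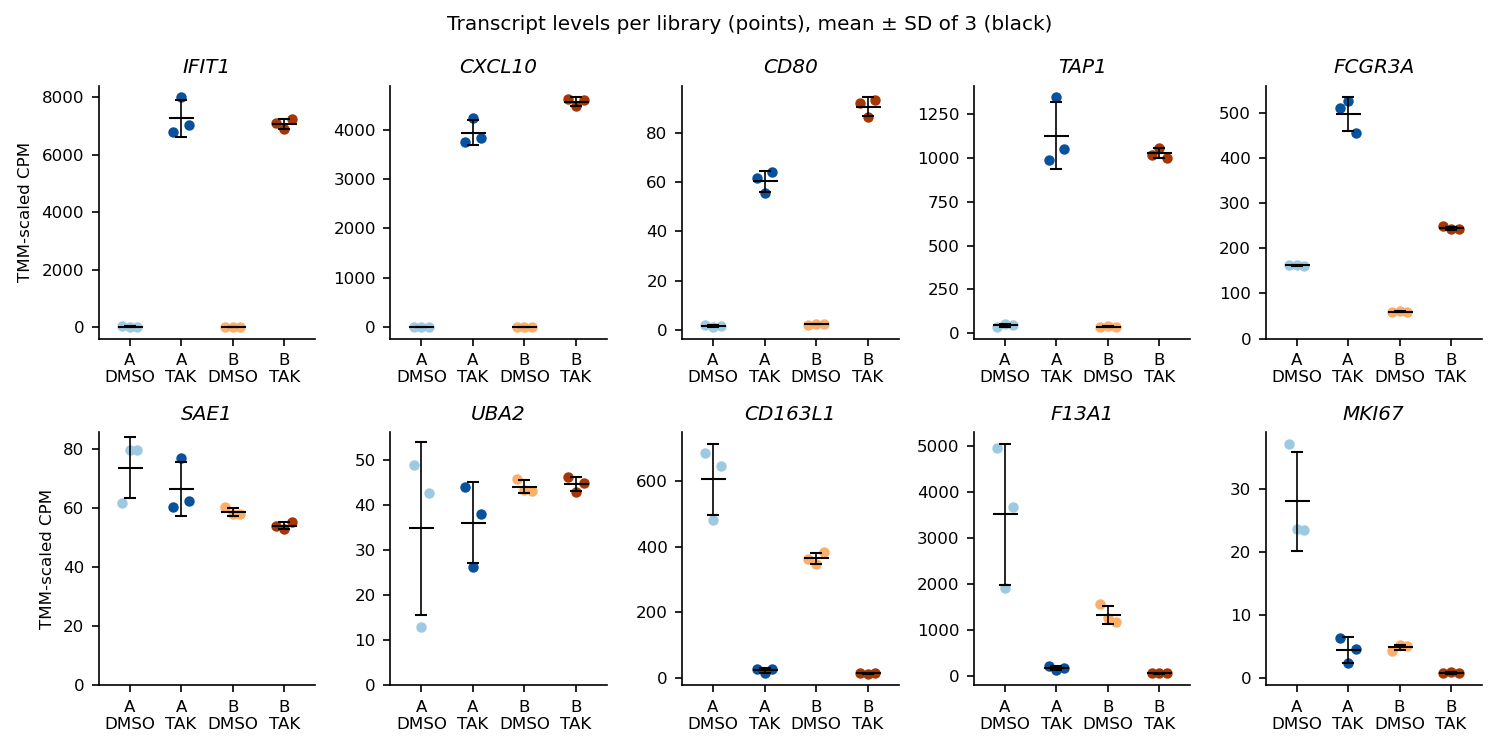
Each panel plots 1 gene as TMM-scaled CPM (vertical axis, linear) per library for the 4 groups of donor and treatment, with the mean ± SD of 3 libraries in black. IFIT1, CXCL10, CD80, TAP1 and FCGR3A are higher and CD163L1, F13A1 and MKI67 lower with TAK-981 in both donors, while SAE1 and UBA2, with log2 fold changes of -0.13 and 0.03 (-0.31 and -0.18 with library totals only), overlap between treatments in donor A, and in donor B UBA2 overlaps and SAE1 lies slightly lower with TAK-981.

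Within the interferon-stimulated list, ISG15, a ubiquitin-like modifier, went from 20.1 ± 19.6 (12.3 without donor A DMSO replicate 2) to 5860 ± 3650 CPM and MX1, an antiviral GTPase gene, from 61.2 ± 23.7 to 3700 ± 161 CPM. ZBP1, which encodes a sensor of Z-form nucleic acid, went from 0.407 ± 0.0786 to 192 ± 8.83 CPM. IRF7, a transcription factor gene of interferon induction, had a log2 fold change of 5.16 ± 0.24. TNFSF10, the gene of the death ligand TRAIL, HERC6 and the RNA sensor gene DDX58 rose by log2 6.56 ± 0.14, 4.42 ± 0.10 and 5.45 ± 0.13. Camera placed the list above all other genes (adjusted p = 1.27e-69, and adjusted p = 0.000434 with an estimated correlation). Adjusted over the list alone 61 members were called. The list took 0.319 ± 0.0483% of all counts with DMSO and 7.44 ± 0.204% with TAK-981 (exact permutation within donors, p = 0.005, the smallest it can give). It was higher in all 6 TAK-981 libraries than in any DMSO library.

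The interferon genes themselves and the sensing machinery were also tested. Of 9 tested genes of type I and III interferons and their receptors, 7 rose and 2 fell (camera adjusted p = 0.0116, and adjusted p = 0.0801 with an estimated correlation; 9 called adjusted over the list alone). IFNE and IFNW1 rose to 1.02 ± 0.349 and 0.294 ± 0.164 CPM, far below IFNB1. The receptor subunit gene IFNAR2 rose from 37.7 ± 4.14 to 83.5 ± 9.10 CPM. IFNL1, a type III interferon, had 4 counts over all 12 libraries and was not tested. Of 24 genes of nucleic acid sensing and interferon induction, 16 rose and 1 fell, with a median log2 fold change of 1.30, and 17 were called adjusted over the list alone. Camera gave adjusted p = 1.68e-06 (adjusted p = 0.00628 with an estimated correlation). They included the DNA sensor gene AIM2, at a log2 fold change of 9.72 ± 0.32, the double-stranded RNA receptor gene TLR3, from 5.61 ± 1.71 to 96.7 ± 25.4 CPM, the adaptor gene MYD88 and the kinase gene IKBKE.

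Among the genes of the Fc-gamma receptors, through which macrophages take up antibody-coated cells, FCGR1A and FCGR3A rose. FCGR1A, the high-affinity receptor gene, went from 85.8 ± 65 to 309 ± 190 CPM (log2 fold change 1.96 ± 0.25, adjusted p = 4.1e-05 in edgeR's test). FCGR3A went from 111 ± 56.5 to 372 ± 141 CPM (1.82 ± 0.10, adjusted p = 2.92e-08). FCGR2A, at 569 ± 25.9 against 489 ± 56.7 CPM, and the inhibitory receptor gene FCGR2B, at 512 ± 170 against 416 ± 94 CPM, did not pass the test (adjusted p = 0.0807 and 0.273). FCGR2A was called in donor A alone (log2 fold change -0.37, adjusted p = 0.0459). Over both donors it passed without the donor A TAK-981 replicate 2 library (-0.25, adjusted p = 0.0493), without both donor A replicate 2 libraries (-0.22, adjusted p = 0.0303) and with DESeq2 (-0.23, adjusted p = 0.0216). With library totals only FCGR2A and FCGR2B both passed (-0.40 and -0.42). The kinase gene LYN and the antibody receptor gene TRIM21 rose by log2 1.99 ± 0.16 and 2.71 ± 0.11, and SYK, the kinase that Fc receptors signal through, fell by 1.16 on the log2 scale. Of the 29 members of the list, 10 rose, 5 fell and 14 did not pass (15 called adjusted over the list alone). The list as a whole did not stand apart from other genes (median 0.145, camera adjusted p = 0.388), though its members moved on balance one way in fry (adjusted p = 2.29e-06), which does not compare them with other genes and called 28 of the 33 lists. Its median was -0.03 with library totals only.

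Transcripts of MHC class I antigen presentation genes rose and class II genes split. In the class I and immunoproteasome list 20 of 22 members rose and none fell, with a median log2 fold change of 1.90, and 20 were called adjusted over the list alone. Camera gave adjusted p = 2.42e-09, and adjusted p = 0.0857 with an estimated correlation. TAP1 and TAP2, the peptide transporter genes, went from 41.2 ± 6.82 to 1080 ± 134 CPM and from 19.5 ± 4.47 to 417 ± 80 CPM. The class I regulator gene NLRC5 rose by log2 2.79 ± 0.17 and HLA-F by 3.05 ± 0.22. In the class II list 3 of 15 members rose and 6 fell (9 called adjusted over the list alone; camera adjusted p = 0.97, with a median of -0.15 and a mean of 0.04). The members that rose included CTSL and LGMN, lysosomal protease genes, at 6160 ± 1150 CPM against 770 ± 147 and at 8070 ± 1030 CPM against 3990 ± 490. HLA-DMB, a peptide-loading factor gene, fell from 701 ± 222 to 204 ± 66.9 CPM.

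Genes of surface molecules that stimulate or restrain T cells rose, and markers of alternative activation went both ways. CD80 and CD86, the genes of both co-stimulatory ligands of CD28, went from 1.95 ± 0.505 to 75.5 ± 17 CPM and from 181 ± 17.1 to 528 ± 81.9 CPM. CD40, a co-stimulatory receptor gene, went from 22.3 ± 8.63 to 182 ± 51 CPM. CD274 and PDCD1LG2, the genes of both ligands of the inhibitory receptor PD-1, rose by log2 5.84 ± 0.18 and 3.52 ± 0.10, and LILRB2, an inhibitory receptor gene, by 2.18 ± 0.08. Of 25 genes in this list 19 rose and 3 fell (22 called adjusted over the list alone), with a median of 2.18. Camera gave adjusted p = 1.35e-11 (adjusted p = 0.00628 with an estimated correlation). Of 22 alternative activation markers 10 rose and 10 fell (20 adjusted over the list alone; camera adjusted p = 0.594, with a median of 0.19 and a mean of -0.42). The mannose receptor gene MRC1, whose reads RSEM divides with a duplicate, fell by 3.48 on the log2 scale, but this value rests on the libraries of 1 donor. The call ended with no donor term, where the log2 fold change was -3.33 (adjusted p = 0.218). F13A1, a coagulation factor gene, fell from 2430 ± 1540 to 123 ± 71.4 CPM and STAB1 from 2300 ± 515 to 686 ± 204 CPM. The transcription factor gene MAF had a log2 fold change of -1.35 ± 0.11, and the lectin gene CD209 rose from 97.8 ± 10.4 to 295 ± 46.8 CPM. CD163, the haemoglobin scavenger receptor gene, stood at 1850 ± 309 against 2390 ± 389 CPM with TAK-981 (log2 fold change 0.37 ± 0.13, adjusted p = 0.0353). The CD163 call ended without donor A TAK-981 replicate 1 or 3 or any 1 of the donor B libraries (0.299 to 0.363, adjusted p = 0.0668 to 0.104). It also ended with library totals only (0.183), with no filter (0.34) and with no donor term.

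The SUMO pathway list as a whole did not stand apart from other genes. Of its 30 tested members 8 rose, 1 fell and 21 did not pass (9 called adjusted over the list alone; median 0.28, camera adjusted p = 0.153, and 0.0324 when no low-count filter was applied). The genes of the target enzyme stayed near their DMSO levels, with SAE1 at 66.1 ± 10.5 against 60.2 ± 9.01 CPM and UBA2 at 39.5 ± 13.2 against 40.4 ± 7.49 CPM (adjusted p = 0.273 and 0.923). With library totals only, SAE1 passed as lower (log2 fold change -0.31, adjusted p = 0.0205) and the value of UBA2 turned from 0.03 to -0.18. SUMO2 and SUMO3, at 0.28 ± 0.11 and 0.28 ± 0.13, did not pass (adjusted p = 0.0514 and 0.0795), but passed without donor A DMSO replicate 2 (adjusted p = 0.0467 and 0.0112) or donor A TAK-981 replicate 3 (0.0304 and 0.0475). SUMO2 also passed without donor A TAK-981 replicate 1 (adjusted p = 0.0473) and with DESeq2 (0.0333). Both passed without both donor A replicate 2 libraries (adjusted p = 0.00705 and 0.00368) and with the replicate number as a block (0.0142 and 0.0115). The members with the smallest p were PML and SP100, nuclear body genes that are also induced by interferon, at log2 3.81 ± 0.16 and 1.91 ± 0.11. The protease gene DESI1 stood at 1.81 ± 0.14, and EGR2 fell by 3.03.

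The list of NF-kB inflammatory cytokine and chemokine genes rose in part, and whether NF-kB drove these changes was not tested. Of 32 members 16 rose, 9 fell and 7 did not pass, with a median of 0.56 (27 called adjusted over the list alone). Camera gave adjusted p = 0.000676, and adjusted p = 0.134 with an estimated correlation. IL27, a cytokine subunit gene, went from 0.0789 ± 0.0478 to 56.5 ± 18.6 CPM. CCL8, a monocyte chemokine gene, went from 7.80 ± 3.14 to 1700 ± 482 CPM, and IL15, a growth factor gene for NK cells, from 1.68 ± 0.204 to 16.4 ± 2.07 CPM. TNFAIP6 rose by log2 5.67 ± 0.13. Complement genes included C1R and C1S, the C1 proteases, which rose by log2 8.53 ± 0.33 and 6.77 ± 0.18. C1R went from 0.0649 ± 0.041 to 25.4 ± 3.54 CPM. Its DMSO mean lay below the highest DMSO floor, 0.0966 CPM, so the size of its rise is uncertain. CFB rose by 4.73 ± 0.21 and the C1 inhibitor gene SERPING1 by 6.08 ± 0.28. In that list 10 of 17 rose and 2 fell (13 adjusted over the list alone; camera adjusted p = 0.000152, and adjusted p = 0.368 with an estimated correlation).

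Genes of cell division fell, and genes of cell death and p53 signalling rose. In the cell cycle and replication list 22 of 30 members fell and 2 rose (27 called adjusted over the list alone), with a median of -1.57. Camera gave adjusted p = 3.53e-06, and adjusted p = 0.368 with an estimated correlation. MKI67, a proliferation marker gene, went from 16.5 ± 13.7 to 2.62 ± 2.38 CPM. MCM6, a replicative helicase gene, went from 40.5 ± 8.75 to 12.3 ± 0.882 CPM, and CDC45 fell by 3.22 on the log2 scale. Of 25 apoptosis regulators 20 rose and 1 fell (21 adjusted over the list alone; median 1.28, camera adjusted p = 1.49e-08, and adjusted p = 0.00146 with an estimated correlation). They included the pro-apoptotic gene BAK1 at log2 2.66 ± 0.11, the anti-apoptotic gene MCL1 at 2.09 ± 0.10, and the caspase genes CASP5 and CASP10 at 5.73 ± 0.26 and 1.58 ± 0.08. Of 24 p53 targets 16 rose and 2 fell (18 adjusted over the list alone; camera adjusted p = 0.00205, and adjusted p = 0.063 with an estimated correlation). CDKN1A, a cell cycle inhibitor gene, went from 43.6 ± 14.1 to 477 ± 55.7 CPM and the death receptor gene FAS from 2.27 ± 0.843 to 52 ± 9.37 CPM. AEN went from 4.87 ± 0.464 to 47.8 ± 1.57 CPM, and BTG2 had a log2 fold change of -1.53 ± 0.11.

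Heat shock protein genes rose in 12 of 16 cases and none fell (12 adjusted over the list alone; median 1.00, camera adjusted p = 0.000324, and adjusted p = 0.0163 with an estimated correlation). The chaperone gene HSPA8 went from 1270 ± 122 to 2940 ± 389 CPM and HSP90AB1 from 470 ± 35.5 to 978 ± 58.2 CPM. The co-chaperone gene DNAJA1 rose by log2 2.41 ± 0.105 and HSPA1B, a near copy of HSPA1A, by 2.51 ± 0.15. Of the glycolysis genes 10 of 21 rose and none fell (10 adjusted over the list alone), with a median of 0.393. Camera gave adjusted p = 0.0358, and adjusted p = 0.678 with an estimated correlation. The call also ended without donor A DMSO replicate 1 (median 0.375, adjusted p = 0.0583) and without both donor A replicate 2 libraries (0.464, adjusted p = 0.0992). It ended too with the replicate number as a block (median 0.399, adjusted p = 0.0799). PFKP went from 16 ± 2.42 to 128 ± 11.6 CPM and LDHA from 389 ± 70.6 to 814 ± 119 CPM. Unfolded protein response and ATF4 targets gave 7 rises and 5 falls of 23 (12 adjusted over the list alone; camera adjusted p = 0.52, with a median of -0.11 and a mean of 0.38). ATF3 stood at log2 4.42 ± 0.14 and TRIB3 at -1.71 ± 0.20. NRF2 targets and metallothioneins gave 7 rises and 4 falls of 20 (11 adjusted over the list alone; camera adjusted p = 0.397), led by the metallothionein gene MT2A, from 5.89 ± 5.88 (3.55 without donor A DMSO replicate 2) to 681 ± 419 CPM.

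Lists of lipid, lysosome and chromatin genes did not stand apart from other genes by camera. Lipid handling genes gave 6 rises and 6 falls of 18 (13 adjusted over the list alone; adjusted p = 0.397). PPARG, a lipid-sensing nuclear receptor gene, fell from 10.9 ± 5.38 to 2.53 ± 1.08 CPM and SCD, a fatty acid desaturase gene, from 688 ± 56.3 to 191 ± 24 CPM. Cholesterol synthesis genes gave 9 rises and 5 falls of 23 (14 adjusted over the list alone; adjusted p = 0.38), with INSIG1 at log2 1.26 ± 0.11 and IDI1 at 0.94 ± 0.09. Lysosome genes gave 3 rises and 10 falls of 28 (12 adjusted over the list alone; adjusted p = 0.397). PSAP, a sphingolipid activator gene, fell from 28100 ± 5620 to 16000 ± 3760 CPM and CTSK from 100 ± 16.6 to 43.8 ± 8.86 CPM. Heterochromatin factors and partners of KRAB zinc finger proteins gave 6 rises and 8 falls of 22 (14 adjusted over the list alone; adjusted p = 0.467), with UHRF1 at -3.82 ± 0.33 and ATF7IP at 2.04 ± 0.28. Germline genes gave 2 rises and 1 fall of 7 (3 adjusted over the list alone; adjusted p = 0.511, median 0.13 and -0.08 with library totals only), with STAG3 at 2.54 ± 0.18. Nuclear-encoded oxidative phosphorylation genes gave 4 rises and 10 falls of 31 (14 adjusted over the list alone; adjusted p = 0.397), with SDHB at 1.63 ± 0.21 and NDUFV1 at -1.07 ± 0.24.

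Transcripts that mark RNA content also moved with treatment. Mitochondrially encoded genes fell in 12 of 13 cases, with MT-CO3 from 3140 ± 590 to 752 ± 157 CPM and MT-CYB from 1980 ± 356 to 470 ± 144 CPM. Adjusted over the list alone 13 were called (median -1.30, camera adjusted p = 0.000152, and adjusted p = 0.324 with an estimated correlation). Their share of counts was 3.87 ± 0.511% with DMSO and 1.53 ± 0.467% with TAK-981 (exact permutation within donors, p = 0.005). It was lower in all 6 TAK-981 libraries than in any DMSO library. Ribosomal protein genes fell in 38 of 53 cases and none rose (40 adjusted over the list alone), with a median of -1.15. Camera gave adjusted p = 0.000226, and adjusted p = 0.683 with an estimated correlation. RPL3 fell from 1090 ± 710 to 252 ± 97.1 CPM. Their share was 3.32 ± 1.89% against 1.27 ± 0.585% (exact permutation within donors, p = 0.01). It was 7.05% and 2.46% in the donor A replicate 2 libraries with DMSO and TAK-981. The 10 highest genes of a library held 20.5 ± 2.34% of counts with DMSO and 13.7 ± 1.57% with TAK-981 (exact permutation within donors, p = 0.005). These p-values were 0.00833, or 0.0125 for the ribosomal share, once adjusted over the 5 permutation tests. Of 9 replication-dependent histone genes 7 rose (7 adjusted over the list alone; median 3.00, camera adjusted p = 2.81e-06, and adjusted p = 0.144 with an estimated correlation). HIST1H2BK went from 4.72 ± 1.93 to 30.7 ± 11.8 CPM and HIST2H2BE from 3.18 ± 0.992 to 17.8 ± 4.22 CPM.

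**Figure D3:**
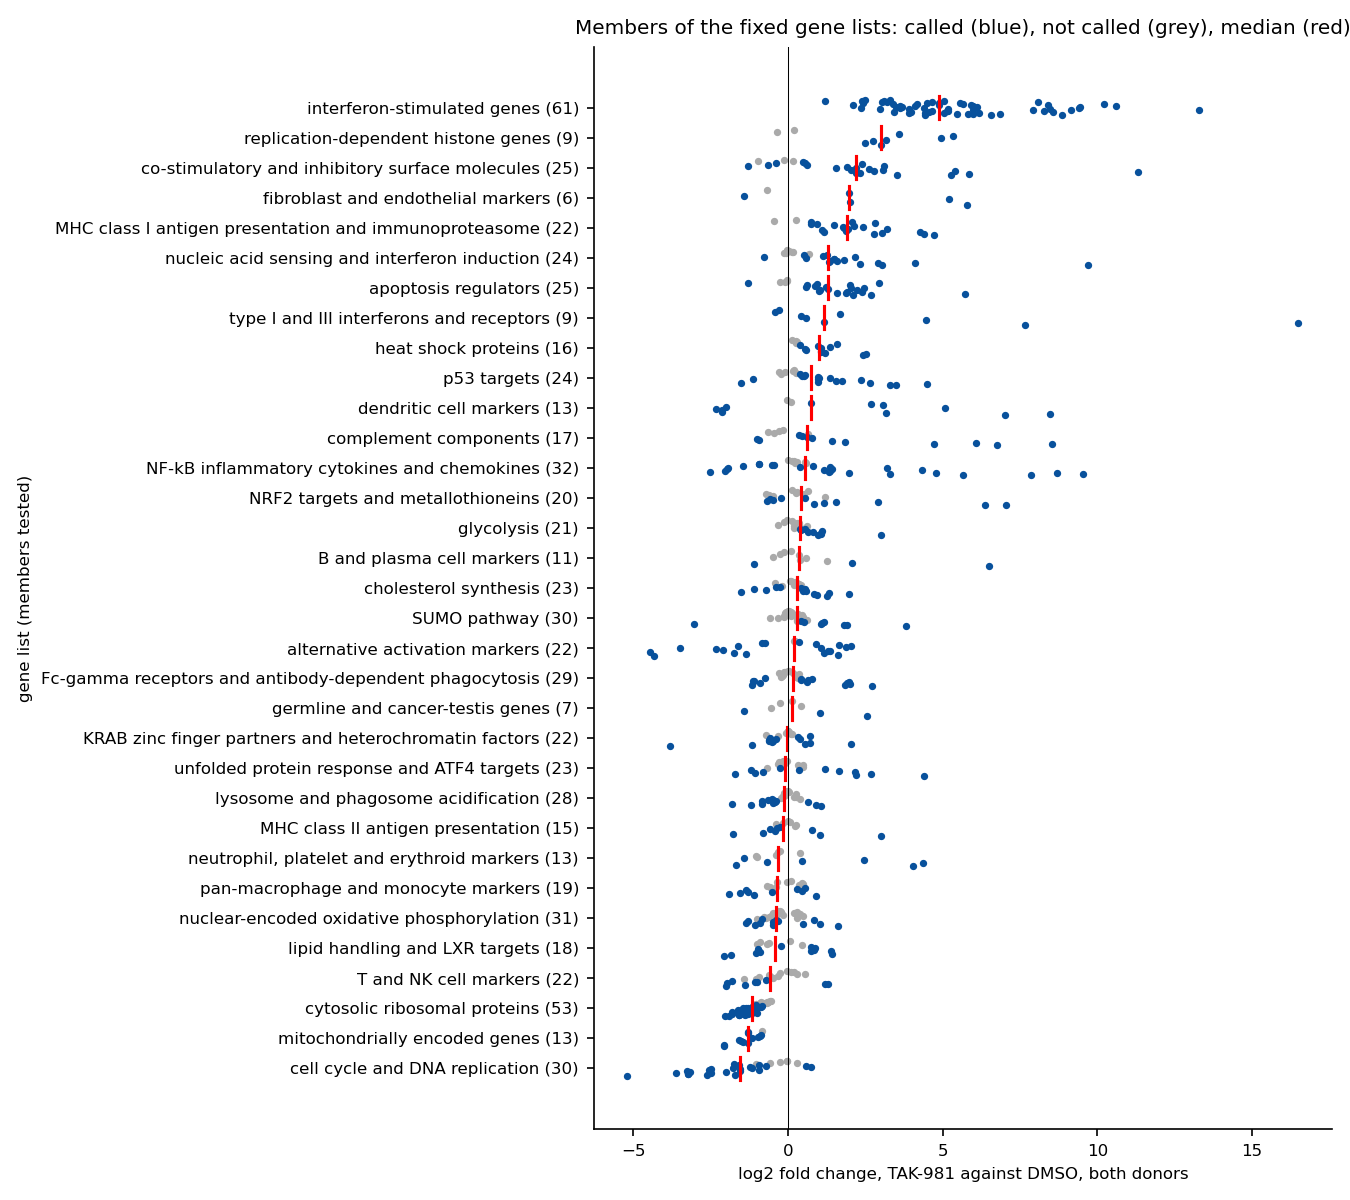
Each row is 1 of the 33 gene lists, with the number of tested members in brackets, and each point is a member at its log2 fold change of TAK-981 over DMSO in both donors (horizontal axis), blue where called and grey where not, with the list median in red. The interferon-stimulated list has the highest median, 4.89, and the cell cycle list the lowest, -1.57; the fitted value of IFNB1, at the far right, has no upper bound because that gene had no count with DMSO.

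Markers of macrophages and of other cell types gave the following values beside these groups. Of 19 monocyte and macrophage markers 4 rose and 6 fell (10 adjusted over the list alone; camera adjusted p = 0.511), with CD68 from 3400 ± 288 to 6400 ± 361 CPM and ITGAX from 423 ± 58.9 to 198 ± 31.6 CPM. Of 22 T and NK cell markers 2 rose and 7 fell (6 adjusted over the list alone; adjusted p = 0.263), with CD28 from 97.8 ± 20 to 24.7 ± 6.22 CPM. Of 11 B and plasma cell markers 2 rose and 1 fell (3 adjusted over the list alone; adjusted p = 0.757). The transcription factor gene PAX5 went from 0.589 ± 0.674 to 34.9 ± 9.63 CPM, and CD79B stood at 2.57 ± 3.72 (1.17 without donor A DMSO replicate 2) against 2.70 ± 1.86 CPM. CD79B did not pass over both donors (adjusted p = 0.162) or in donor A (log2 fold change -0.34), and was called in donor B (3.34, adjusted p = 0.00214). Over both donors it passed without donor A DMSO replicate 2 (adjusted p = 0.0124), without both donor A replicate 2 libraries (0.0229), with DESeq2 (0.0412) and as the mean of the within-donor contrasts (0.0116). Of 13 dendritic cell markers 7 rose and 4 fell (11 adjusted over the list alone; adjusted p = 0.172). The cytokine receptor gene IL3RA went from 0.282 ± 0.0772 to 37.6 ± 11.6 CPM and ZBTB46 from 5.92 ± 1.69 to 1.33 ± 0.249 CPM. Neutrophil, platelet and erythroid markers gave 4 rises and 3 falls of 13 (7 adjusted over the list alone; adjusted p = 0.998, with a median of -0.33 and a mean of 0.38), with AZU1 at -1.69 ± 0.25. Fibroblast and endothelial markers gave 4 rises and 1 fall of 6 (5 adjusted over the list alone; adjusted p = 0.102), with TAGLN from 6.56 ± 1.89 to 26.2 ± 5.29 CPM. This list passed without donor A DMSO replicate 2 or 3, donor B DMSO replicate 1, 2 or 3, or donor B TAK-981 replicate 2 or 3 (adjusted p = 0.0225 to 0.0465), and with library totals only (adjusted p = 0.0266).

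The second comparison took each donor alone, and the responses ran in the same direction for nearly all genes called. Interferon-stimulated genes had median log2 fold changes of 4.76 in donor A and 5.13 in donor B, and IFIT1 rose by 8.13 ± 0.33 and 8.96 ± 0.34. MX1 rose by 5.57 ± 0.32 in donor A and 6.38 ± 0.33 in donor B, CD80 by 5.24 ± 0.22 and 5.29 ± 0.22, and CD163L1 fell by 4.70 and 4.63 on the log2 scale. In edgeR's test 6505 genes were called in donor A, 3309 higher and 3196 lower, and 6352 in donor B, 3396 higher and 2956 lower. Higher calls shared by both donors numbered 2860, against 692 for independent lists of those sizes, and lower calls 2398 against 582. Calls in both donors rest on the same estimate of each gene's spread, which alone can raise this overlap. Of 7590 genes called in either donor 98.2% had the same sign in the other. Fold changes of the 16233 genes correlated across genes at r = 0.904 (Spearman's rho = 0.887), with no library shared between the donors. With each donor fitted on its own 6 libraries the counts were 3018 in donor A and 12388 in donor B, and without both donor A replicate 2 libraries 9878 and 11127.

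**Figure D4:**
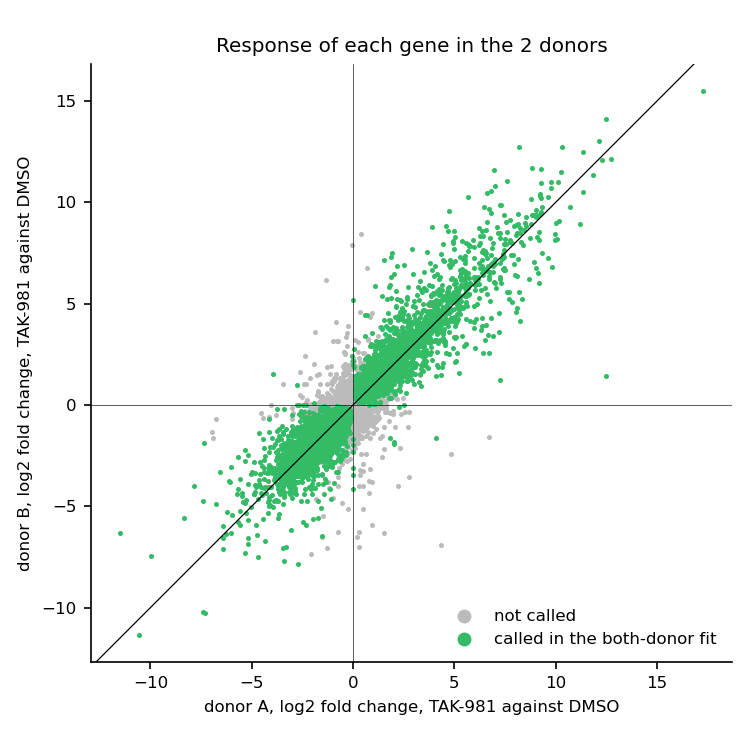
Each point is 1 of 16233 genes at its log2 fold change of TAK-981 over DMSO in donor A (horizontal axis) and donor B (vertical axis), green where called over both donors, with the line of equal change. Points follow the line, with r = 0.904 across genes.

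The difference of the response between donors was tested as an interaction. ANPEP, which encodes a surface aminopeptidase, rose by log2 2.11 ± 0.16 in donor A and 3.78 ± 0.17 in donor B (difference 1.67, adjusted p = 0.0237). TGM2, a transglutaminase gene, rose by 3.03 ± 0.15 and 1.01 ± 0.14 (difference -2.02, adjusted p = 0.009). TNFAIP2, a gene induced by TNF, had a log2 fold change of 1.41 ± 0.30 in donor A and -1.54 ± 0.30 in donor B (difference -2.95, adjusted p = 0.0342). TCF19, a gene of the G1 to S transition, fell in donor A (-1.14 ± 0.12) and did not pass in donor B, with 0.29 ± 0.12 in donor B (difference 1.43, adjusted p = 0.0198). In edgeR's quasi-likelihood test 20 genes passed, 15 with the higher value in donor B and 5 in donor A, beside 807 at an unadjusted p below 0.05. No gene passed without donor A DMSO replicate 3, donor B DMSO replicate 3 or any 1 of the donor B TAK-981 libraries. There were 2 without donor A TAK-981 replicate 1 or 3 or donor B DMSO replicate 1, 3 without donor B DMSO replicate 2, 65 without donor A DMSO replicate 2, 35 without donor A TAK-981 replicate 2 and 21 without donor A DMSO replicate 1. DESeq2 called 201 genes, 286 passed without both donor A replicate 2 libraries and 224 with the replicate number as a block.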

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

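Of the tests in this part, those of transcript length and of sequencing depth in the donor A replicate 2 libraries were chosen after the result was seen, and so were leaving out those 2 libraries together, the splits of the gene lists with an estimated correlation and the exchanges that keep the donors' levels.

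The difference of the TAK-981 response between donors was singled out because its own test called 20 genes. Among these, the named genes ANPEP and TCF19 differed by log2 1.67 and 1.43 in favour of donor B, and TNFAIP2 and TGM2 differed by -2.95 and -2.02, in favour of donor A. Exchanging libraries between donors within each treatment in 100 splits, the real one included, gave as many as 20 genes in 1 split, the real one, and at most 3 genes in the others. That alone decides nothing, since exchanged libraries bring their own donor's levels and widen the groups. With each exchanged library first set to the other donor's level by the additive donor term, 1 of 100 splits, the real one, gave as many as 20 genes and the highest other 0. That does not exclude chance either, since donor A libraries, which varied more within a group, widen the donor B groups they are moved into. Leaving out any 1 of 5 libraries left no gene called. The 4 differences kept their sign under every alternative run. ANPEP, TCF19 and TNFAIP2 missed the threshold without donor A DMSO replicate 3, donor A TAK-981 replicate 1 or 3, or any 1 of the donor B libraries, with differences of 1.51 to 1.72, 1.33 to 1.43 and -3.03 to -2.75. TGM2 missed it without donor A DMSO replicate 3, donor B DMSO replicate 3 or any 1 of the donor B TAK-981 libraries, at -2.10 to -2.01. With library totals only, ANPEP, TCF19 and TNFAIP2 also missed the threshold (1.47, 1.30 and -3.09), as did ANPEP and TCF19 with no filter (1.60 and 1.36). With 2 donors the differences belong to these 2 sets of cultures, and no biological explanation was tested.

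The number of genes called depended on 2 libraries that stand apart. The donor A replicate 2 libraries of both treatments had low levels of long transcripts: the log2 ratio to their siblings fell with transcript length over 12224 genes, with Spearman's rho of -0.214 with DMSO and -0.238 with TAK-981. In the donor B libraries this rho lay between -0.117 and 0.13. The other donor A libraries gave 0.131 to 0.233, but their siblings include a replicate 2 library, so these values partly mirror it. Lower sequencing depth does not account for it, since siblings thinned to the same total still held at least 1640 more genes with a count. Summed markers of other cell types gave no sign of such cells in both libraries. No list of T and NK, B, dendritic, granulocyte, platelet and erythroid, or stromal markers exceeded its siblings in both libraries by more than 0.0667 CPM. A sum can come mostly from a single gene, as from PAX5 in the B list with TAK-981, so a small share of other cells is not excluded. Monocyte and macrophage markers were not compared in this way, so a different share of monocytes was not tested. S100A9, 1 of these markers and picked after its value was seen, stood at 1900 CPM in the DMSO library, against a mean of 332 CPM in the other DMSO libraries. In the TAK-981 library it stood at 498 CPM, against 120 CPM in the other TAK-981 libraries. A candidate explanation is RNA or library quality that lowered long transcripts in both libraries, which the rho of -0.214 or lower goes with, but the labels give no quality value to test it. The column label of the TAK-981 library carries a code number that differs from the other 11, with no meaning given, and 1 library is too few for a value within a batch, while the DMSO library has the common number. Without the pair, 12062 genes were called over both donors, 8858 of them among the 8900, and 286 in the difference between donors, including all 20.

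Other splits of the libraries were also run for the treatment comparisons. Over both donors 1 of 100 splits within donors, the real one, called as many as 8900 genes and the highest other split called 3848, so chance can be excluded at that share. Within donor A 1 of 10 splits called as many as 6505 genes and the highest other 4243, and within donor B 1 of 10 as many as 6352 and the highest other 0. These 10 splits per donor are too few for a share below 0.05. For the gene lists with the preset correlation, 8 of 100 splits, the real one among them, called as many as 15 lists and the highest other called 16, which leaves open whether chance can be excluded for that number. The 7 other splits kept 4 of the 6 libraries of each treatment in place, so the 7 carry part of the treatment difference and do not stand for chance. The 41 splits that kept 3, with both treatments equally on each side, called a median of 3 lists and at most 7. Camera with the preset correlation thus called some lists where the sides were balanced for treatment. Both donor A replicate 2 libraries were on opposite sides in the 7 other splits. With an estimated correlation 1 of 100 splits, the real one, called as many as 5 lists and the highest other 0. The interferon-stimulated list had a smaller camera p in the real split than in the other 99, where the smallest was 3.68e-25.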

How the results depend on the processing

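Leaving out both donor A replicate 2 libraries was chosen after seeing the data. The counts over both donors stayed within 1.5 times under all alternatives run, in total and per direction, and the interferon-stimulated list and the shares of counts kept their direction and their side of the threshold. The Fc-gamma receptor list never passed in camera. Of 3437 log2 fold changes over both donors of the 164 named genes under alternatives, 3394 kept their side of the threshold, 21 no longer passed and 22 newly passed, and no value that passed in either fit changed sign. The cause of the changes below was not tested, except that fits on fewer libraries estimate the spread from those libraries. With an estimated correlation 10 of the 15 called lists no longer passed, the class I list (median 1.90) and the NF-kB list (0.561) among them, and with no filter the SUMO list passed (0.252). The genes with a different response between donors numbered 13 with no filter (8 higher in donor B), 43 with at least 50 counts in 3 libraries (32 and 11), 201 with DESeq2 (125 and 76; 342 genes had no adjusted p), 286 without both donor A replicate 2 libraries (190 and 96), and 0 to 65 with 1 library left out (0 to 48 and 0 to 17). The correlation between donors was 0.617 with no filter and 0.828 to 0.893 with 1 library left out. With only its own libraries donor A gave 3018 genes (1667 higher, 1351 lower) and donor B 12388 (6161 and 6227). Without both donor A replicate 2 libraries donor A gave 9878 (4987 and 4891) and donor B 11127 (5668 and 5459). The replicate numbers were not taken to pair the samples, since not all 6 pairs deviated together: deviations of same-numbered libraries correlated at 0.741, 0.726 and 0.293 in donor A, but at -0.04, 0.04 and 0.03 in donor B, and not every library correlated best with its own number. With the replicate block donor A gave 10148 genes (5105 and 5043), donor B 10059 (4983 lower) and the difference between donors 224 (145 and 79). With it SUMO2, SUMO3 and FCGR2A newly passed (adjusted p = 0.0142, 0.0115 and 0.0421) and the glycolysis list no longer passed (adjusted p = 0.0799). A count of 3 stood for 0.0418 to 0.0966 CPM, depending on the library.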

Other observations

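Of the tests in this part, those of scaling, of mRNAs with a 5' terminal oligopyrimidine (TOP) motif, of S phase and of non-polyadenylated RNA, and the families by symbol, were chosen after the results were seen.

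Gene families that share the start of their symbol were tested by camera, for the 119 families with at least 12 tested genes. There were 5 families that passed. Genes whose symbol starts with IRF, the interferon regulatory factors and the IRF2BP genes, rose in 9 of 12 cases and fell in 1, with a median log2 fold change of 1.53 (adjusted p = 0.000184, and adjusted p = 0.136 with an estimated correlation). Poly(ADP-ribose) polymerase family genes (PARP) rose in 10 of 13 cases and fell in 2, with a median of 1.18 (adjusted p = 0.00643, and adjusted p = 0.99 with an estimated correlation). Histone genes (HIST) rose in 22 of 27 cases and none fell (median 2.5, adjusted p = 2.25e-06, and adjusted p = 0.622 with an estimated correlation). Genes whose symbol starts with RPL or RPS, among them pseudogenes and RPS6K kinase genes beside the ribosomal proteins, fell in 49 of 83 and 33 of 57 cases and rose in 2 and 3 (medians -1.10 and -1.05, adjusted p = 0.00633 and 0.0321). Neither passed with an estimated correlation (adjusted p = 0.99 for both).

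A total of 46 tested genes had no count in any DMSO library, and those named here were chosen after their values were seen. CSAG3, a gene of a cancer-testis family, reached 7.08 ± 4.44 CPM with TAK-981 (SD, n = 6), at least 73.2-fold higher against 3 counts per library, and CSAG2 and CSAG1 reached 0.821 ± 0.994 and 0.483 ± 0.346 CPM; the CSAG genes share sequence, so the division between them is uncertain. BCL2L14, an apoptosis-related gene, was at least 29.7-fold higher, EPHA7 at least 14.3-fold and BTC, a growth factor gene, at least 10-fold.

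Ribosomal protein transcripts fell, with a median of -1.15 over both donors and -0.88 in donor B, which has no library standing apart. A loss of short transcripts does not account for it, since random lists matched on length and expression had a median of 0.327 in donor B (95% of them between 0.00852 and 0.729). A scaling shift, which moves all genes alike, does not account for it either, since the list lay at -1.11 relative to the median of all genes with TMM. RLE and library totals gave -1.12 and -1.06, but this difference hardly depends on the scaling, so they add no separate evidence. In donor B 24 other protein-coding genes with TOP mRNAs had a median of -0.704 against 0.327 for matched lists (95% between -0.103 and 0.768), and -0.775 together with 8 non-coding TOP transcripts. The matched lists were drawn gene by gene. Their 95% range is therefore too narrow for genes that vary together, as those of the ribosomal list do (estimated correlation 0.992). Over both donors 18 of the 24 fell and 1, VIM, rose (named after their values were seen, PABPC4 at -2.25 ± 0.11 and EIF4B at -2.01 ± 0.15). The hypothesis that TAK-981 may lower TOP mRNAs as a class goes with these values, but it was found and tested on the same data, and the ribosomal list lost its call with an estimated correlation (adjusted p = 0.683).

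Replication-dependent histone transcripts rose, with a median of 3.00, while cell cycle genes fell, and both lists lost their call with an estimated correlation (adjusted p = 0.144 and 0.368). More cells in S phase do not account for it, as the cell cycle list had a median of -1.57 with 22 of 30 members lower. RNAs of other kinds without poly(A) tails did not rise with the histone transcripts, as 11 such RNAs had a median of -0.445 (quartiles -1.13 and 0.04). Their median level was 0.657 CPM, only 5 reached 1 CPM, and the library preparation is not given, so this argues only weakly against carry-over of such RNA. A gain of short transcripts is argued against, since lists matched on length and expression had a median of -0.179 (95% between -0.996 and 0.747, for the 8 of 9 genes with a length). A hypothesis that stays open is that TAK-981 may change the synthesis, the processing or the polyadenylation of histone mRNAs apart from replication. That hypothesis was not tested, and neither were reads shared between near-identical histone genes. Whether the histone transcripts measured here carried poly(A) tails is not known from these data.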
